A study of Homo sapiens with 18 samples.

How the data were processed

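ChIP-seq with an anti-GFP antibody (8 libraries with a deposited list of called regions, 2 for each of 4 FOXP2-EGFP constructs in HEK293 cells) was used; 9 inputs and a control ChIP, 10 of 18 samples, are not used here. Cells were fixed in 1% formaldehyde for 10 minutes and sonicated, per the labels' protocols. Reads were handled with Bowtie2 2.5.1, SAMtools 1.13 and MACS2 2.2.9.1 on build hg38, per the submitters' processing notes, which give no settings. How the lists were filtered, which input served each library and how deep each was sequenced are not given in the sources used here. In every list some of the caller's running peak numbers are absent, between 43 and 254 of them, so some peaks were taken out after calling. Replicates were not pooled, since each list carries the name of a single library.

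Each deposited line holds a region, its summit offset, a score, the authors' fold enrichment (a ratio to the local background at the summit) and the authors' −log10 p-value and −log10 q-value. The deposited score was 10 times the −log10 q-value cut to a whole number, in all but at most 4 lines of a list. The highest q in each list was close to 0.05. Lines that share a region (several summits in 1 region) were joined, and the summit with the highest fold was kept. Folds were turned into percentiles within each list and were never compared between lists as changes in binding. The lists give regions above a threshold only, so a place outside a list can still be bound below it, and a list with fewer regions can come from lower depth, lower enrichment or less binding alike.

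Coordinates are 1-based on hg38. Gene positions came from a RefSeq gene table of assembly GRCh38.p14, with 59716 placed genes, of which 19974 protein-coding genes were used. The table gives no strand, exons or transcripts, so the planned distance to a transcription start was replaced by the distance to either end of a gene, and classes of exon, intron and UTR were not used here. No genome sequence was used here, so the planned searches for forkhead, MAF and SOX motifs, other motifs and enriched 8-mers were not run.

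Libraries were grouped by construct from their titles. Replicate numbers equal the batch label in every construct, so the numbers pair libraries across constructs by batch. As a check of the pairing, the mean Jaccard index of different constructs was 0.175 within a batch and 0.182 across batches, and the gene-end share was higher in batch 2 for 3 of 4 constructs (by 5.31 points in R553H, 4.51 in R553H-MAFK and 7.09 in R553H-Sox2, with WT at -0.522).

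Before the data were examined, the following were fixed, except that gene ends later took the place of transcription starts and a single strongest summit stood for each region. Similarity of libraries was the Jaccard index of covered base pairs, tested by an exact permutation over all pairings of the 8 libraries (one-sided). A reproducible peak was the merged region of a replicate-1 and a replicate-2 region that overlap by at least 50% of the shorter. A peak was shared with another construct when it overlapped a region of either of its libraries by that much, and without counterpart when not 1 bp overlapped. Expected values came from 100 shuffles within chromosomes (20 for the position classes). The gene-end share of R553H was tested against the other 6 libraries by an exact permutation (two-sided). A gene was occupied when a summit of a reproducible peak lay within 5 kb of either end. Each of 15 gene lists (reported FOXP2 targets, FOXO-type forkhead targets, antioxidant genes, pluripotency and neural genes, cell cycle, polyglutamine disease, housekeeping, immediate-early and stress, axon guidance, Wnt, tissue-restricted, neuronal effector, ribosomal proteins, histones and olfactory receptors) was tested against all other protein-coding genes by Fisher's exact test, two-sided, in each construct. The p-values were adjusted by the Benjamini-Hochberg method over the 60 tests, with a threshold of 0.05. Genes that share a peak or a cluster are not independent, and these p-values do not allow for that. All listed names matched the gene table. 95% Wilson intervals cover counting error only.

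Sites are named by a rule set at the same time: in each construct, the 8 reproducible peaks with the highest mean fold percentile; in each comparison with R553H, the 8 highest without counterpart on each side and the 8 highest reproducible in both, at most 1 per gene and each named by the protein-coding gene with the nearest end within 50 kb; up to 4 genes per list, taken by the same percentile; and FOXP2, MAFK and SOX2. The block inside FOXP2 and the narrow region inside MAFK were singled out after their values were seen. Some sites that the rule takes are not reported here.

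Alternatives were other overlap rules, stricter q or fold limits, equal-length lists (the 4054 strongest regions, or the 3634 highest reproducible peaks), other distances to gene ends, batch-blocked permutations, and leaving out replicates. Alternatives chosen after seeing the data were identity without each library, all summits in place of the strongest, 1 gene of a list per 100 kb and lists without chromosome 6. Also chosen then were R553H represented by replicate 1 alone in the counts without a counterpart, and shuffles that shift regions by 100 kb to 1 Mb. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and figures used matplotlib 3.10.9. On simulated data, shuffled regions of replicate 1 of each construct were shared with a copy at a known rate. A true share of 60.1168% in R553H-MAFK was recovered as 60.0999%, the largest miss of the 8 simulated shares. The copies' ends were moved only slightly, so near-full recovery was fixed in advance. In the libraries compared for the FOXP2 block, ends of strong shared regions differed by a median of 478.5 bp. Gene lists were simulated on shuffled regions of WT replicate 1. Enriched lists of 30 genes with an odds ratio of 5 were called at an unadjusted 0.05 in 100% of draws. Lists without enrichment were called in 4.5%. These lists drew genes independently, so they do not cover lists of clustered genes. Nor do they cover smaller lists, lower odds ratios or adjusted p-values, so they do not measure the power of the tests reported here.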

Results

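Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured where EGFP-tagged forms of FOXP2, a forkhead transcription factor that carries a polyglutamine tract, were recovered on DNA in HEK293 cells, a human embryonic kidney cell line. The 4 constructs were wild-type FOXP2 (WT), FOXP2 with the substitution R553H in its DNA-binding forkhead domain, and 2 forms of R553H named for an added MAFK or Sox2. MAFK is a small MAF basic leucine zipper protein and SOX2 is an HMG-box factor of pluripotent and neural progenitor cells, each with a DNA-binding domain of its own. The question was where a FOXP2 with a damaged DNA-binding domain is found, and where it is found once another factor is attached. Each construct was immunoprecipitated with an anti-GFP antibody in 2 replicates, and replicate 1 and replicate 2 carry the batch labels 1 and 2 for every construct. The labels do not say whether replicates came from separate cultures. The permutation p-values therefore measure only the spread between these libraries, which may be technical. The gene-list p-values compare genes within a construct and do not measure that spread. The 9 input samples and the anti-GFP ChIP of control cells, 10 of the 18 samples, are not analysed here, and so no background list stands beside the values.

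The lists of called regions held 32909 and 30581 regions for WT, 19892 and 4054 for R553H, 72924 and 51184 for R553H-MAFK, and 30143 and 33428 for R553H-Sox2, in the order of replicates 1 and 2. They covered between 2.08 Mb, in R553H replicate 2, and 67.9 Mb, in R553H-MAFK replicate 1. The lists give no read counts, so the depth behind each is unknown and a number of regions is a description of the list. With 2 libraries against 2, the smallest two-sided exact p for a difference between constructs is 0.333, so these numbers were not tested. Fold enrichments named in what follows are the authors' values at each summit, and they rank regions within their own list only. Folds of different lists set side by side therefore do not show a difference in binding. Each site is named by the nearest gene end within 50 kb, so a named site need not lie at that gene.

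On average, libraries of the same construct shared more of their covered sequence than libraries of different constructs, but the R553H pair did not. The mean Jaccard index, shared base pairs over the union, was 0.335 for the 4 same-construct pairs and 0.178 for the other pairs. Of all ways to pair the 8 libraries, none gave a higher mean than the real pairing (exact permutation test, one-sided p = 0.0095, the smallest this design can give). Within pairings that join the batches, p was 0.0417, again the smallest possible. WT replicates had the highest index, 0.452, followed by R553H-Sox2 at 0.402 and R553H-MAFK at 0.383. The R553H replicates had an index of only 0.102, below the mean of 0.178 for different constructs. R553H replicate 1 had a higher index with every library of the other constructs. These ran from 0.1325 with R553H-MAFK replicate 1 to 0.348 with WT replicate 1. R553H replicate 2 covered the least sequence of all libraries. Of the regions of R553H replicate 2, 93.4% were found again in replicate 1, but 18.3% of the regions of replicate 1 were found in replicate 2.

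**Figure D1:**
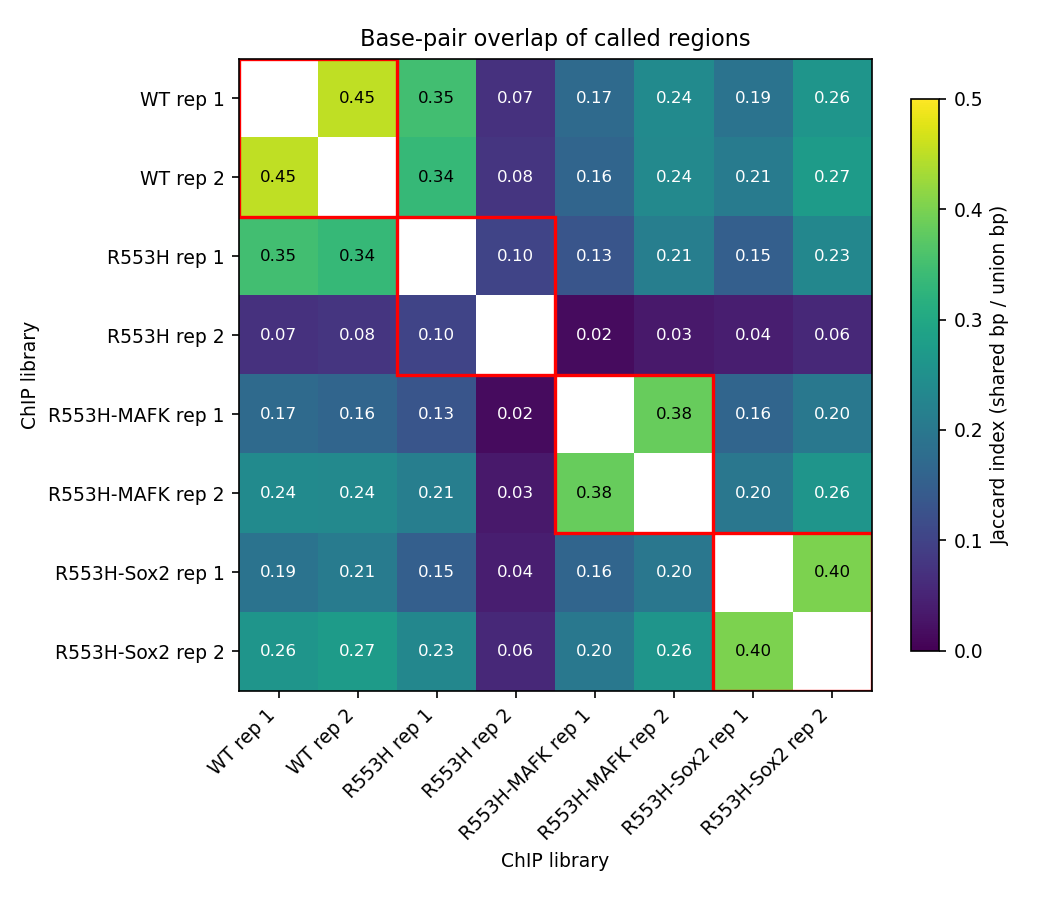
Jaccard index of covered base pairs for each pair of the 8 ChIP libraries, on a colour scale from 0 to 0.5, with red frames around the pairs of the same construct. The WT, R553H-MAFK and R553H-Sox2 pairs lie at 0.452, 0.383 and 0.402, and the R553H pair at 0.102.

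Regions found in both replicates of a construct, called reproducible peaks here, numbered 21330 for WT, 3634 for R553H, 35679 for R553H-MAFK and 20149 for R553H-Sox2. After shuffling regions within their chromosomes, at most 3.39% of replicate-2 regions met a replicate-1 region in any construct. Shifting regions by 100 kb to 1 Mb instead gave at most 4.86%. The observed shares lay between 60.6% and 93.4%. The R553H number cannot exceed the number of regions in its short second replicate.

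A larger share of the R553H regions than of the regions of other constructs lay at the ends of protein-coding genes. Summits within 1 kb of either end of a gene made up 41.4% ± 3.75 (SD, n = 2) of R553H regions, 22.0% ± 0.369 of WT regions, 10.3% ± 3.19 of R553H-MAFK regions and 9.41% ± 5.02 of R553H-Sox2 regions. Shuffled regions gave between 2.62% and 3.06%. Inside genes but farther from their ends lay 31.6% ± 2.60 of R553H regions, 42.2% ± 0.462 of WT regions, 56.2% ± 2.47 of R553H-MAFK regions and 53.8% ± 3.61 of R553H-Sox2 regions. The R553H gene-end share exceeded the mean of the other 6 libraries by 27.5 percentage points (exact permutation test over 28 splits of the libraries, two-sided p = 0.0357, the smallest possible). Keeping the batches apart, the same difference had an exact p of 0.0625, the smallest that design allows. Without R553H replicate 1 the difference was 30.2 points and without replicate 2 it was 24.9 points, each with an exact p of 0.143, again the smallest possible. With lists held to their 4054 strongest regions, R553H replicate 1 fell to 24.9% and the highest of the other libraries was 16.6%. That limit is the whole R553H replicate-2 list, so its 44.1% could not change. Counted by gene, R553H peaks lay within 1 kb of the ends of 9.37% of protein-coding genes, against 30.1% in WT, 22.5% in R553H-MAFK and 7.75% in R553H-Sox2, and R553H replicate 1 alone reached 43.3% against 40.3% in WT replicate 1. R553H-Sox2 replicate 1 alone reached 9.04% and replicate 2 alone 22.4%. Within every list of the 4 constructs the gene-end share was highest in the lowest of 5 groups by fold. In WT replicate 1 it was 38.9% in the lowest group and 10.8% in the highest. The same groups had 53.1% and 24.7% in R553H replicate 1, and 24.8% and 6.91% in R553H-Sox2 replicate 2. The R553H-MAFK lists had no steady fall, with 10.1% and 8.58% in replicate 1 and 16.2% and 13.9% in replicate 2.

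**Figure D2:**
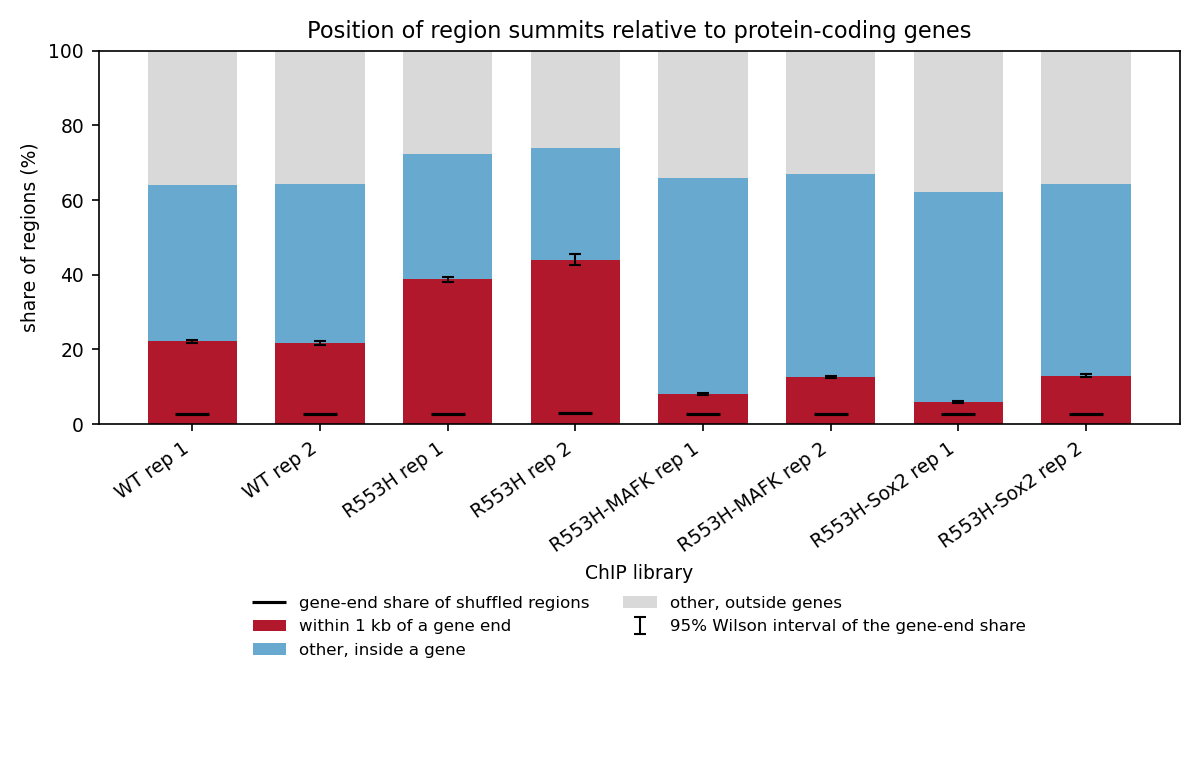
Share of region summits (%) within 1 kb of an end of a protein-coding gene, elsewhere inside a gene, or outside genes, for each of the 8 libraries. Error bars are 95% Wilson intervals of the gene-end share, which cover counting error only, and black dashes show shuffled regions; both R553H libraries, at 38.8% and 44.1%, lie above the other 6.

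The strongest WT site lay between genes on chromosome 18 at 79563455 to 79565403, 34.8 kb from the nearest end of NFATC1, which encodes a calcium-regulated transcription factor of T cells and heart valves. It had the highest fold of both WT lists, 68.1 and 61.6. Next came a site 38.7 kb from MLANA, a melanocyte gene, with folds of 46.3 and 47.7, a site inside DNHD1 with 43.3 and 41.7, and a site 23.5 kb outside VPS41, a gene of lysosomal transport, with 41.2 and 37.9. Among the 8 strongest, the sites at TNRC18, 0.175 kb from the gene's end, and at NPL, 0.878 kb inside it, were the only ones within 1 kb of a gene end. Of the 8 strongest R553H sites, 6 had no protein-coding gene end within 50 kb, the highest of them on chromosome 6 at 11269447 to 11270935 inside a gene, with folds of 17.2 and 10.8. The named ones were TNRC18, at 11.8 and 12.8, and SP4, which encodes a zinc-finger factor related to SP1, at 11.1 and 8.42.

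In the full lists, WT and R553H shared most R553H sites, while many WT sites had no R553H counterpart. Of 3634 R553H peaks, 96.9% overlapped a WT region, and of 21330 WT peaks, 57.2% overlapped an R553H region. With lists of equal length these shares were 55.3% and 46.3%, so most of the difference was gone. Such lists also keep only the strongest regions of longer lists, so length alone was not tested. Sites named for TNRC18, SH3GLB1, SAXO1, GAS1, NFIB, APLP2, SEMA3C and SP4 led those reproducible in both. In WT the SH3GLB1 summit lay 26.5 kb outside the gene. Those inside APLP2, SP4, SEMA3C and SAXO1 lay 33.7, 38.2, 45.3 and 49.2 kb from a gene end. GAS1, a growth-arrest gene, had folds of 24.6 and 26.5 in WT and 9.05 and 6.201 in R553H at a site 0.239 kb from its end. NFIB, a nuclear factor I gene, had 15.9 and 18.2 in WT and 12.9 and 5.83 in R553H at an intragenic site. The highest WT peaks that no R553H region touched lay 4.78 kb from NSFL1C, with folds of 31.6 and 28.5, and 5.32 kb from KDF1, a gene of epidermal differentiation, with 32.2 and 26.0. FAM98C, BFSP1, LILRB4, MREG, ELANE and WSCD1 followed, with ELANE, the neutrophil elastase gene, at 20.1 and 19.99 on chromosome 19 at 856002 to 857518. In all, 8965 WT peaks met no R553H region. Their gene-end share was 6.87% (95% Wilson interval 6.37 to 7.41), against 37.9% (37.1 to 38.8) for the WT peaks that did. In the other direction, 103 R553H peaks met no WT region, led by peaks near ANKRD62, SLC4A4, FABP6, ENPP1, GABRE, URAD and PRKAR1A. The folds were 6.89 and 4.18 at ANKRD62 and 5.18 and 2.89 at PRKAR1A, at mean fold percentiles of 93.7 and 73.2 within the R553H lists. With replicate 1 alone standing for R553H, 9053 WT peaks met no R553H region, and 3609 of all 19892 regions of that list met no WT region, a number that counts every region of a single list in place of reproducible peaks. Library against library, 44.1% of WT regions were found in R553H in batch 1 and 10.7% in batch 2, and 72.1% and 83.03% of R553H regions were found in WT. Shuffled peaks gave at most 1.22% and 3.27%.

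A large set of R553H-MAFK peaks lay where no R553H region was called, and the R553H lists were the shorter ones. The strongest R553H-MAFK sites lay inside ZNF3, a zinc-finger gene, at 24.4 and 29.5, inside ARHGAP35 at 23.2 and 32.2, and 17.7 kb outside MOCS3, a molybdenum cofactor gene, at 22.0 and 28.3. SIRT4, TMEM107, HSF2BP, DEPTOR and PLA2G6 completed the 8 strongest. The sites named for ARHGAP35, on chromosome 19 at 46990906 to 46992054, MOCS3, HSF2BP and DEPTOR, an mTOR inhibitor gene, touched no R553H region. Neither did those named for CIROZ, ADAM33 and ARMC2. The DEPTOR site lay 33.8 kb outside the gene. In total 23347 of 35679 R553H-MAFK peaks touched none, 4.84% (4.57 to 5.12) of them at gene ends, while 32.0% of R553H-MAFK peaks overlapped an R553H region, and 23.8% (23.0 to 24.6) of those lay at gene ends. TNRC18, SP4, NFIB, SAXO1, NRP1, RDX, APLP2 and RSPO2 led the shared sites. NRP1, a receptor for semaphorins and VEGF, had folds of 11.0 and 10.4 in R553H-MAFK and 7.80 and 6.09 in R553H. Its mean fold percentiles were 99.6 in R553H-MAFK and 99.0 in R553H. Of R553H peaks, 82.4% overlapped an R553H-MAFK region and 499 touched none, of which 71.7% (67.6 to 75.5) lay at gene ends. With lists of equal length, which differ in strength as well, the shares were 47.7% for R553H in R553H-MAFK and 42.7% for the reverse. The 499 were led by HCN2, a pacemaker channel gene, at 8.28 and 9.08, followed by ZNF467, SHC2, TMEM276-ZFTRAF1, NCBP3, RTP5, GNPTG and ZNF639. With R553H replicate 1 alone, 23431 R553H-MAFK peaks and 4319 R553H regions had no counterpart, and 60.5% of the latter lay at gene ends. Library against library, 16.9% of R553H-MAFK regions were in R553H in batch 1 and 5.45% in batch 2, and 62.6% and 70.9% of R553H regions were in R553H-MAFK. Shuffled peaks gave at most 1.4% for R553H-MAFK in R553H and 5.86% for R553H in R553H-MAFK.

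Genes of the antioxidant response, whose promoters carry the elements that small MAF proteins bind together with NRF2, were occupied by R553H-MAFK at 21 of 30 (70.0%, against 42.9% of other protein-coding genes; Fisher's exact test, two-sided, adjusted exact p = 0.0141). The strongest of them were BLVRB at 11.3 and 10.3, GSR at 8.62 and 9.43, SLC7A11 at 8.55 and 8.48, and TXNRD1 at 7.89 and 8.19. BLVRB and GSR encode biliverdin and glutathione reductases, SLC7A11 the cystine transporter and TXNRD1 thioredoxin reductase. Constructs without MAFK shared most of these sites. The GSR and TXNRD1 sites were also peaks in WT and R553H-Sox2, and the BLVRB site overlapped a WT peak. At TXNRD1 the folds were 16.8 and 15.6 in R553H-Sox2 and 6.90 and 9.19 in WT, at mean fold percentiles of 99.8 and 95.6. In WT 17 of these 30 genes were occupied (adjusted exact p = 0.141), in R553H-Sox2 11 (adjusted exact p = 0.0636) and in R553H 5 (adjusted exact p = 0.623). The differences between constructs in this list were not tested, and R553H replicate 1 alone occupied 20 of the 30. With genes counted up to 50 kb from a summit, the R553H-MAFK call was lost (27 of 30, adjusted exact p = 0.209). At that distance WT, with 30 of 30 (adjusted exact p = 6.32e-04), and R553H-Sox2, with 24 of 30 (adjusted exact p = 0.0403), passed. The R553H-MAFK call held within 1 kb (adjusted exact p = 0.0337). It also held with equal numbers of peaks, at 37.6 points above other genes (adjusted exact p = 5.93e-08). WT (adjusted exact p = 0.146) and R553H (adjusted exact p = 0.726) did not pass there.

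R553H-Sox2 likewise had many peaks where no region was called in the shorter R553H lists. Its top site, at both replicates' highest fold of 41.6 and 55.6, lay 0.126 kb outside MTF2, a Polycomb-associated gene, on chromosome 1 at 93078641 to 93080823. KCNA1, a potassium channel gene, had a site 44.9 kb away at 29.9 and 28.6, TNRC18 had 23.5 and 40.9, and MYH4 had 28.5 and 21.3. KCNA1 also led the R553H-Sox2 peaks that touched no R553H region, followed by RIPK4, APOBEC3B, ZNF157, TWIST2, PSG1, SYN3 and DHX57. At TWIST2, a mesenchymal transcription factor gene, the folds were 14.1 and 18.2. There were 12433 such peaks among 20149, of which 3.0% (2.71 to 3.31) lay at gene ends. A further 36.9% of R553H-Sox2 peaks overlapped an R553H region, with 14.0% (13.2 to 14.8) at gene ends. TNRC18, CRNN, SAXO1, NFIB, APLP2, SEMA3C, VANGL2 and ARHGEF12 led the shared sites, and VANGL2, a planar cell polarity gene, had 13.7 and 21.8 in R553H-Sox2 and 7.65 and 7.02 in R553H. Conversely, 74.8% of R553H peaks overlapped an R553H-Sox2 region and 878 touched none, 69.9% (66.8 to 72.9) of them at gene ends. With lists of equal length the shares were 43.1% for R553H in R553H-Sox2 and 38.7% for the reverse. HCN2 and ZNF467 led the 878 again, then BCL2L11, a pro-apoptotic BH3 gene and FOXO target, at 6.37 and 4.88, TMEM276-ZFTRAF1, ARAP2, AVPI1, CES4A and GNPTG. R553H replicate 1 alone gave 12488 R553H-Sox2 peaks and 8029 R553H regions without a counterpart. Library against library, 26.5% of R553H-Sox2 regions were in R553H in batch 1 and 7.75% in batch 2, and 38.8% and 65.0% of R553H regions were in R553H-Sox2. Shuffled peaks gave at most 1.03% for R553H-Sox2 in R553H and 3.22% for R553H in R553H-Sox2.

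Of 24 genes known from pluripotent and neural progenitor cells, R553H-Sox2 occupied 8 (33.3%, against 19.8% of other genes; Fisher's exact test, adjusted exact p = 0.167), which did not pass. They included NEUROG2 at 5.73 and 6.53, NOTCH1 at 4.89 and 9.67, SOX2 itself at 5.46 and 5.55, and ZFP42 at 4.61 and 5.08. WT occupied 13 of the 24 (adjusted exact p = 0.284), R553H 6 (adjusted exact p = 0.165; 12 in replicate 1 alone) and R553H-MAFK 8 (adjusted exact p = 0.476). Axon guidance genes were occupied by R553H-Sox2 at 17 of 36 (47.2% against 19.8%, adjusted exact p = 9.46e-04), among them EFNA1 at 7.26 and 8.73, NRP2 at 7.14 and 6.52, and PLXNA2 at 6.64 and 6.33. In this list WT had 20 of 36 (adjusted exact p = 0.140), R553H-MAFK 22 (adjusted exact p = 0.0547) and R553H 9 (adjusted exact p = 0.0726), and the differences between constructs were not tested. R553H replicate 1 alone occupied 22 of the 36. Within 1 kb of gene ends the R553H-Sox2 call was lost, with 4 of 36 genes (adjusted exact p = 0.4996), as it was with equal numbers of peaks (3 of 36, adjusted exact p = 0.209).

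Apart from R553H, the constructs also shared sites with each other. Of WT peaks, 74.4% overlapped an R553H-MAFK region and 61.6% an R553H-Sox2 region, and 56.9% of R553H-MAFK peaks overlapped an R553H-Sox2 region, against at most 4.48% after shuffling. With lists of equal length these shares were 36.7%, 35.5% and 40.2%. Library against library, in batches 1 and 2, these shares were 57.2% and 58.2%, 36.4% and 49.2%, and 27.6% and 38.2%. The reverse shares in the full lists were 52.3% for R553H-MAFK in WT, 63.0% for R553H-Sox2 in WT and 85.0% for R553H-Sox2 in R553H-MAFK. Sites in all 4 constructs made up 39.7% of WT peaks, 68.6% of R553H peaks, 23.95% of R553H-MAFK peaks and 33.7% of R553H-Sox2 peaks. The site 0.175 kb from TNRC18, on chromosome 7 at 5423395 to 5427599 in WT, was among the strongest of WT, R553H and R553H-Sox2 and led the shared sites of every comparison with R553H. At the other extreme, 10114 R553H-MAFK peaks (28.3%), 3143 WT peaks (14.7%), 2150 R553H-Sox2 peaks (10.7%) and 48 R553H peaks (1.32%) touched no region of another construct.

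Immediate-early and stress-response genes had the highest occupied share of the 15 gene lists in WT, R553H and R553H-MAFK with all reproducible peaks within 5 kb. In R553H-MAFK within 1 kb the ranking did not hold, with cell-cycle genes 35.9 points above other genes and immediate-early genes 27.5. Nor did it hold in R553H replicate 1 alone, with 22 of 24 immediate-early and 23 of 24 housekeeping genes. A gene was counted as occupied when a reproducible summit lay within 5 kb of either of its ends, which held for 41.3% of protein-coding genes in WT, 12.9% in R553H, 42.9% in R553H-MAFK and 19.8% in R553H-Sox2. The R553H rate rests on its short second replicate, since without it about 53.0% of the genes outside a list were occupied. Of 24 immediate-early and stress genes, WT occupied 23 (adjusted exact p = 1.40e-07), R553H 18 (adjusted exact p = 4.85e-11), R553H-MAFK 22 (adjusted exact p = 4.66e-06) and R553H-Sox2 10 (adjusted exact p = 0.0346). HSP90AA1, a heat-shock chaperone gene, had folds of 10.7 and 11.3 in WT and 5.68 and 5.08 in R553H. MYC had 7.02 and 6.52 in WT and 6.61 and 3.79 in R553H. The mean fold percentiles were 98.7 in WT and 96.3 in R553H for HSP90AA1, and 93.0 and 90.6 for MYC. DUSP1, a MAP kinase phosphatase gene, led the list in R553H-MAFK at 10.2 and 9.43 and in R553H-Sox2 at 8.26 and 8.39. From R553H-Sox2 replicate 1 alone the call was lost (adjusted exact p = 0.0591), as it was without chromosome 6 (adjusted exact p = 0.171), within 50 kb (adjusted exact p = 0.112) and with 1 gene per 100 kb (adjusted exact p = 0.0579). With every construct held to its 3634 highest reproducible peaks, as many as R553H has, the R553H-MAFK call was lost (3 of 24, adjusted exact p = 0.296), and histone genes there stood 47.8 points above other genes (adjusted exact p = 2.53e-27). Differences between constructs were not tested in any list.

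Genes known as FOXO-type forkhead targets passed the test in all constructs, but not under every alternative. Of 20 genes known as targets of FOXO-type forkhead factors, 14 were occupied in WT (adjusted exact p = 0.0258), 7 in R553H (adjusted exact p = 0.0246), 15 in R553H-MAFK (adjusted exact p = 0.0146) and 10 in R553H-Sox2 (adjusted exact p = 0.0075). FBXO32, a muscle ubiquitin ligase gene, had folds of 12.3 and 18.1 in WT and 7.86 and 4.25 in R553H. PIK3CA, a PI3-kinase subunit gene, had 7.77 and 8.78 in WT and 5.82 and 4.87 in R553H. The mean fold percentiles were 99.5 in WT and 94.5 in R553H for FBXO32, and 96.4 and 95.9 for PIK3CA. Of 18 genes reported as FOXP2 targets, R553H occupied 7 (38.9% against 12.9%, adjusted exact p = 0.0145), WT 10 (adjusted exact p = 0.304), R553H-MAFK 12 (adjusted exact p = 0.0917) and R553H-Sox2 6 (adjusted exact p = 0.200). The site at an end of FOXP1, a close relative of FOXP2, had folds of 16.7 and 15.2 in WT and 5.83 and 5.61 in R553H. Its mean fold percentiles were 99.7 in WT and 97.4 in R553H. HES1, a Notch target, had folds of 6.51 and 5.95 in R553H. Within 1 kb the R553H call was lost (5 of 18, adjusted exact p = 0.0503) and R553H-MAFK passed (9 of 18, adjusted exact p = 0.0261), as it did within 50 kb (18 of 18, adjusted exact p = 0.0458). With R553H replicate 1 alone, 11 of the 18 were occupied and the call was lost (adjusted exact p = 0.722), as it was for the FOXO-type list (15 of 20, adjusted exact p = 0.118). The FOXO-type call was also lost in WT within 1 kb (9 of 20, adjusted exact p = 0.257) and within 50 kb (adjusted exact p = 0.0517), in R553H within 50 kb (adjusted exact p = 0.0973), in R553H-MAFK without chromosome 6 (adjusted exact p = 0.0518) and in R553H-Sox2 with equal numbers of peaks (adjusted exact p = 0.242).

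Replication-dependent histone genes were occupied at 57 of 73 in WT (adjusted exact p = 1.42e-09), 18 in R553H (adjusted exact p = 0.0192), 63 in R553H-MAFK (adjusted exact p = 1.87e-13) and 56 in R553H-Sox2 (adjusted exact p = 2.11e-24). A merged region on chromosome 6 at 26025059 to 26034362 had its R553H-MAFK summit 0.372 kb from an end of H4C2, at folds of 18.1 and 18.2. R553H replicate 1 alone occupied 59 of the 73. Most of these genes lie in clusters on chromosome 6, and without that chromosome 9 of 18 remained in WT (adjusted exact p = 0.606) and 5 of 18 in R553H (adjusted exact p = 0.124). The R553H-MAFK call held there, at 36.0 points above other genes (adjusted exact p = 0.011). Counting at most 1 histone gene per 100 kb left 14 genes. It also ended the call in WT (adjusted exact p = 0.0579), R553H (adjusted exact p = 0.0572) and R553H-MAFK (adjusted exact p = 0.0917). The differences from other genes were then 30.3, 22.9 and 28.7 points in that order, against 36.9, 11.8 and 43.6 with the whole list. With equal numbers of peaks the call was lost in R553H-Sox2 (3 of 73, adjusted exact p = 0.647) and WT (adjusted exact p = 0.311), and within 1 kb in R553H (10 of 73, adjusted exact p = 0.334). Wnt pathway genes passed in every construct, but in none under all alternatives, with 20 of 32 in WT (adjusted exact p = 0.0373), 11 in R553H (adjusted exact p = 0.0057), 21 in R553H-MAFK (adjusted exact p = 0.0258) and 12 in R553H-Sox2 (adjusted exact p = 0.0445). TCF7L2 had 9.74 and 10.5 in WT and FZD3, a Frizzled receptor gene, 11.6 and 9.34 in R553H-MAFK. The Wnt call was lost in WT without replicate 1 (adjusted exact p = 0.118) or replicate 2 (adjusted exact p = 0.125), in R553H without replicate 2 (adjusted exact p = 0.125) and in R553H-MAFK without replicate 2 (adjusted exact p = 0.0591). In R553H-Sox2 it was lost with 1 gene per 100 kb (adjusted exact p = 0.0552). Within 50 kb it was lost in WT (adjusted exact p = 0.133), R553H (adjusted exact p = 0.067) and R553H-MAFK (adjusted exact p = 0.0653), and within 1 kb in R553H (adjusted exact p = 0.225) and R553H-MAFK (adjusted exact p = 0.245). With equal numbers of peaks it was lost in WT (adjusted exact p = 0.0581), R553H-MAFK (adjusted exact p = 0.589) and R553H-Sox2 (1 of 32, adjusted exact p = 0.732).

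Housekeeping genes were occupied at 18 of 24 in WT (adjusted exact p = 0.0051), 9 in R553H (adjusted exact p = 0.0068) and 19 in R553H-MAFK (adjusted exact p = 0.0025), and at 7 in R553H-Sox2 (adjusted exact p = 0.368). Ribosomal protein genes followed, with 51 of 83 in WT (adjusted exact p = 0.0014), 47 in R553H-MAFK (adjusted exact p = 0.0301), 14 in R553H (adjusted exact p = 0.317) and 9 in R553H-Sox2 (adjusted exact p = 0.0678). The housekeeping call was lost within 50 kb in WT (adjusted exact p = 0.240) and R553H-MAFK (adjusted exact p = 0.0578), and in WT its direction turned with equal numbers of peaks (1 of 24, adjusted exact p = 1). The ribosomal call was lost in WT with equal numbers of peaks (adjusted exact p = 0.732), and in R553H-MAFK it was lost with 1 gene per 100 kb (adjusted exact p = 0.0579) and turned with equal numbers (3 of 83, adjusted exact p = 0.732), while R553H passed within 50 kb (35 of 83, adjusted exact p = 0.0403). EEF2, a translation elongation factor gene, had folds of 5.52 and 4.09 in WT and 10.9 and 8.98 in R553H-MAFK, at mean fold percentiles of 76.2 and 99.3. Cell-cycle and mitosis genes were occupied at 18 of 24 in R553H-MAFK (adjusted exact p = 0.0060), led by MAD2L1 at 6.42 and 7.95 and CCNA2 at 6.47 and 7.64, at 12 in WT (adjusted exact p = 0.476), 3 in R553H-Sox2 (adjusted exact p = 0.513) and 2 in R553H (adjusted exact p = 0.787). The cell-cycle call in R553H-MAFK was lost within 50 kb (22 of 24, adjusted exact p = 0.226) and with equal numbers of peaks (2 of 24, adjusted exact p = 0.734). R553H replicate 1 alone gave other values for these groups, with 23 of 24 housekeeping genes, 21 of 24 cell-cycle genes (adjusted exact p = 0.0021) and 73 of 83 ribosomal protein genes (adjusted exact p = 1.99e-10) occupied. R553H-Sox2 replicate 1 alone placed the ribosomal protein genes below other genes (11 of 83, adjusted exact p = 0.033), and replicate 2 alone did not (31 of 83, adjusted exact p = 1). R553H-Sox2 replicate 2 alone also occupied 12 of the 24 cell-cycle genes and 14 of the 24 housekeeping genes.

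Olfactory receptor genes and genes known from other tissues were mostly unoccupied. Olfactory receptor genes were occupied at 5 of 390 in WT (adjusted exact p = 2.08e-80), 1 in R553H (adjusted exact p = 2.69e-21), 7 in R553H-MAFK (adjusted exact p = 2.64e-81) and 6 in R553H-Sox2 (adjusted exact p = 9.93e-28), below other genes each time. Genes restricted to other tissues, such as globin, albumin and troponin genes, were occupied at 4 of 36 in WT (adjusted exact p = 6.64e-04) and 0 in R553H (adjusted exact p = 0.0258), below other genes, and at 10 in R553H-MAFK and 3 in R553H-Sox2, which did not pass (adjusted exact p = 0.140 and 0.141). These calls changed with the setting: R553H-MAFK passed below other genes from replicate 2 alone (11 of 36, adjusted exact p = 0.0183) and from replicate 1 alone (12 of 36, adjusted exact p = 0.0253), and R553H-Sox2 from replicate 2 alone (7 of 36, adjusted exact p = 0.0468) and within 50 kb (adjusted exact p = 0.0119). The R553H call was lost within 1 kb (adjusted exact p = 0.0945) and with 1 gene per 100 kb (adjusted exact p = 0.0574), and the WT call with equal numbers of peaks (adjusted exact p = 1). Neuronal effector genes did not differ from other genes by this test, with 8 of 24 in WT (adjusted exact p = 0.590), 4 in R553H (adjusted exact p = 0.590), 11 in R553H-MAFK (adjusted exact p = 0.852) and 6 in R553H-Sox2 (adjusted exact p = 0.638), although SNAP25, a synaptic vesicle fusion gene, had folds of 19.6 and 15.7 in R553H-Sox2. Nor did the 9 genes of polyglutamine expansion diseases pass, with 6 in WT (adjusted exact p = 0.234), 2 in R553H (adjusted exact p = 0.392), 4 in R553H-MAFK (adjusted exact p = 1) and 4 in R553H-Sox2 (adjusted exact p = 0.135). With equal numbers of peaks R553H-MAFK passed there (3 of 9, adjusted exact p = 0.0402). R553H replicate 1 alone occupied 5 of the 36 tissue-restricted, 6 of the 390 olfactory receptor, 14 of the 24 neuronal effector and 8 of the 9 polyglutamine disease genes. Among the last, TBP, the TATA-binding protein gene, had 14.4 and 13.1 in WT.

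**Figure D3:**
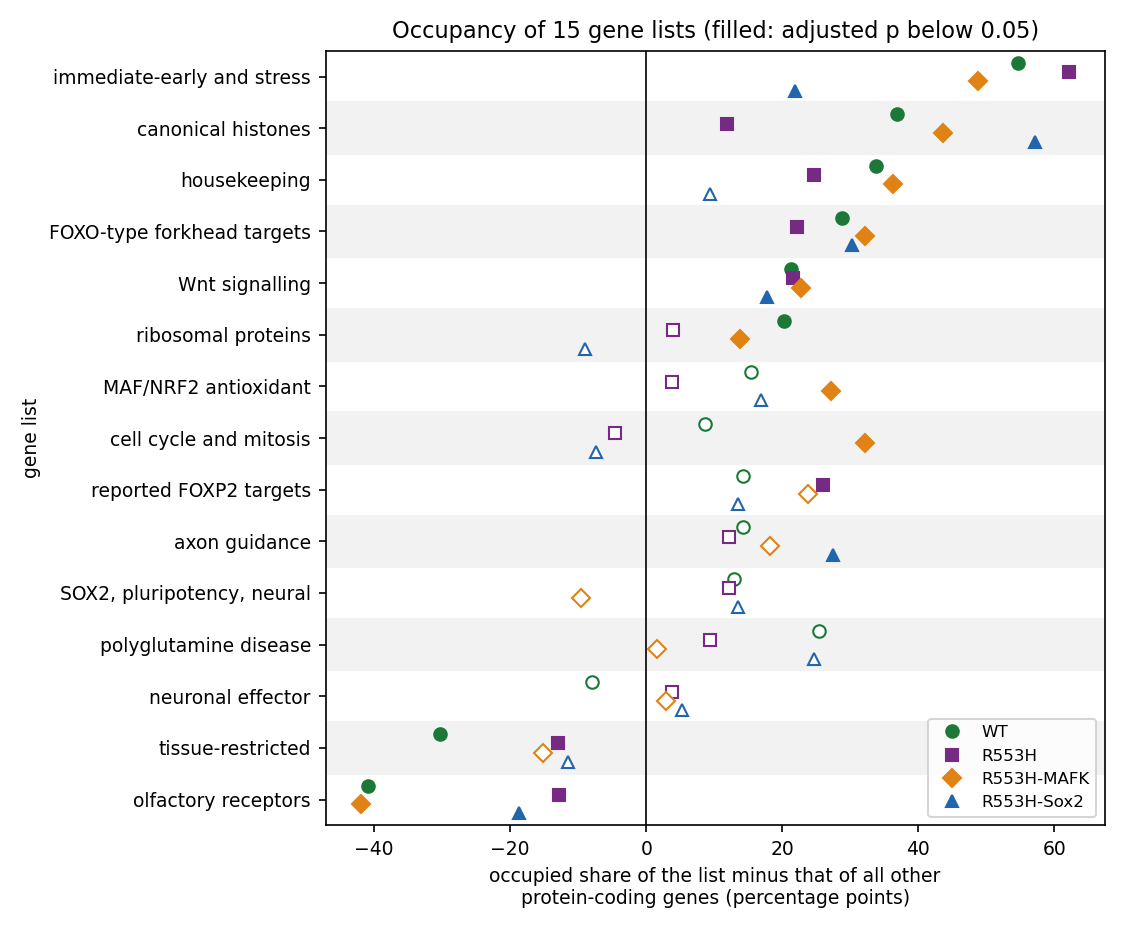
Occupied share of each of 15 gene lists minus the occupied share of all other protein-coding genes, in percentage points, for the 4 constructs. Filled symbols mark adjusted p below 0.05 (Fisher's exact test, 60 tests); immediate-early genes lie to the right in every construct, from 21.9 points in R553H-Sox2 to 62.2 in R553H, and olfactory receptor genes to the left.

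The gene that each construct carries was examined in every library. FOXP2 (gene 93986, chromosome 7, 114086327 to 114693765) held 12 and 15 regions in WT, 21 and 9 in R553H, 56 and 28 in R553H-MAFK, and 15 and 15 in R553H-Sox2. In WT the strongest sat over the gene's start coordinate, at folds of 11.5 and 11.5. In R553H, R553H-MAFK and R553H-Sox2 replicate 2 the strongest was a block of about 3.2 kb inside the gene, from 114628531 to 114631715 in R553H, with folds of 38.2, 16.3 and 30.7. It was the strongest region of the whole R553H replicate-2 list. Replicate 1 of these constructs held only weaker, shorter regions there (R553H at 3.50, R553H-MAFK at 3.19 and 2.36) or none (R553H-Sox2), WT replicate 1 had none, and WT replicate 2 had a region of 962 bp at 5.53. MAFK (gene 7975, chromosome 7, 1530702 to 1543043) held 1 to 3 regions in every library. A region of 436 bp inside it, at 1539943 to 1540378 with a fold of 8.35, was called in R553H-MAFK replicate 2 and in none of the other libraries. SOX2 (gene 6657, chromosome 3, 181711925 to 181714436) held 1 or 2 regions in every library, with strongest folds of 5.46 and 5.55 in R553H-Sox2, 2.66 and 5.92 in WT, 2.95 and 3.21 in R553H, and 5.55 and 4.25 in R553H-MAFK.

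**Figure D4:**
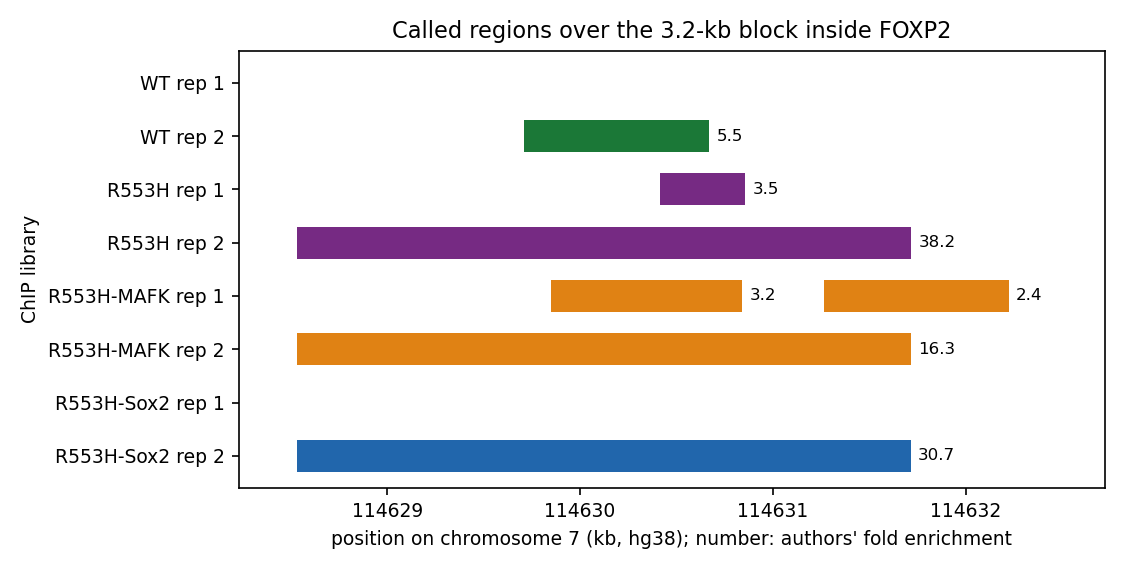
Called regions of each of the 8 libraries over the 3.2-kb block inside FOXP2, as bars on chromosome 7 coordinates (kb, hg38), each with the authors' fold enrichment. The block spans the same positions in replicate 2 of R553H, R553H-MAFK and R553H-Sox2, at folds of 38.2, 16.3 and 30.7.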

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

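The alternatives chosen after the data were seen were identity without each library, all summits, 1 gene per 100 kb and lists without chromosome 6. The local shift shuffle and the counts without a counterpart for R553H replicate 1 alone were also chosen then. The rest were fixed before, among them gene lists from a single replicate. For the main results, 70 values kept their direction and side of the threshold or stayed within their spread, 3 lost the threshold and 69 moved. For the 60 gene-list results, 359 were unchanged in call, 46 lost and 12 gained a call, and 3 reversed. A further 20 values changed sign while not called under either setting, and are counted among the 359. Also among them are the R553H values with equal numbers of peaks. Their differences could not move, because that number is the whole R553H list. The cause was not tested for any value unless stated. The motif alternatives were not run, for lack of a genome sequence.

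Mean same-construct similarity stayed above mean different-construct similarity under every alternative run. The difference was 0.153 for pairs that join the batches, 0.2295 for equal-length lists and 0.18 at −log10 q of at least 5. It was 0.172 for the share of the smaller list, and 0.128 to 0.253 leaving out a library. Without a library of WT, R553H-MAFK or R553H-Sox2, another pairing matched or exceeded the real one (exact permutation test, one-sided p = 0.019 to 0.0381). Without R553H-MAFK replicate 1, for example, another pairing reached a mean of 0.329 against 0.319 for the real pairs.

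The batch block left the R553H gene-end difference at 27.5 points and raised the exact p to 0.0625, because only 16 splits remain. Leaving out a library gave 24.9 to 30.2 points. For overlaps, the mean of the within-batch shares was 27.4% for WT in R553H, 77.6% for R553H in WT, 11.2% for R553H-MAFK in R553H, 66.8% for R553H in R553H-MAFK, 17.1% for R553H-Sox2 in R553H, 51.9% for R553H in R553H-Sox2, 57.7% for WT in R553H-MAFK, 42.8% for WT in R553H-Sox2 and 32.9% for R553H-MAFK in R553H-Sox2. Leaving out a replicate gave, in that order, 10.7 to 44.1, 72.1 to 83.03, 5.45 to 16.9, 62.6 to 70.9, 7.75 to 26.5, 38.8 to 65.0, 57.2 to 58.2, 36.4 to 49.2 and 27.6 to 38.2%. Both compare single lists, so they are lower by construction. The local shift shuffle gave at most 8.34% for any overlap, reached by R553H in R553H-MAFK, where shuffles within chromosomes gave at most 5.86%.

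Reproducible peaks fell with stricter limits by construction: at −log10 q of at least 5 to 12605 in WT, 1654 in R553H, 17521 in R553H-MAFK and 12875 in R553H-Sox2, and at fold of at least 5 to 4010, 155, 4061 and 3993. With 50% of both regions R553H had 1182, and with summits within 100 bp R553H had 2264 and R553H-MAFK 21010.

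Requiring 50% of both regions gave overlaps of 48.5% for WT in R553H, 16.5% for R553H-MAFK in R553H, 58.1% for R553H in R553H-MAFK (86.3% with 1 bp), 29.1% for R553H-Sox2 in R553H, 49.3% for R553H in R553H-Sox2, 57.6% for WT in R553H-MAFK, 45.6% for WT in R553H-Sox2 and 26.0% for R553H-MAFK in R553H-Sox2. At −log10 q of at least 5 WT in R553H was 47.3%, R553H in R553H-MAFK 80.4%, R553H-Sox2 in R553H 30.2%, WT in R553H-MAFK 65.9% and WT in R553H-Sox2 55.1%. With equal-length lists WT in R553H was 46.3%, R553H in WT 55.3%, R553H-MAFK in R553H 42.7%, R553H in R553H-MAFK 47.7%, R553H in R553H-Sox2 43.1%, WT in R553H-MAFK 36.7%, WT in R553H-Sox2 35.5% and R553H-MAFK in R553H-Sox2 40.2%. The gap between WT in R553H and R553H in WT, 57.2% against 96.9%, thus narrowed to 46.3% against 55.3% at equal length. Without R553H replicate 2, R553H regions outside WT, R553H-MAFK and R553H-Sox2 rose from 103, 499 and 878 to 3609, 4319 and 8029, since all regions of a single list then count.

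Gene lists above other genes went from 6 to 2 in WT, 8 to 5 in R553H-MAFK and 5 to 1 in R553H-Sox2 with equal numbers of peaks, which leave fewer occupied genes. They went from 6 to 3 in R553H within 1 kb, from 8 to 5 in R553H-MAFK within 50 kb, and from 5 to 3 in R553H-Sox2 with 1 gene per 100 kb. Housekeeping genes in WT reversed to -0.776 points (adjusted exact p = 1) and ribosomal protein genes in R553H-MAFK to -2.22 points (adjusted exact p = 0.732) with equal numbers of peaks. Cell-cycle genes in R553H reversed to 34.6 points without replicate 2 (adjusted exact p = 0.0021), and leaving out replicate 1 gave -5.19 points. The lists hold no read counts, so what depth limits could not be measured.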

Other observations

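Of the tests given here, the prediction that fewer sites of the same kind pass the threshold in R553H replicate 2 was tested as written beforehand; the other 5 tests of explanations and the tRNA counts were chosen after the result was seen.

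Transfer RNA genes, which RNA polymerase III transcribes, had reproducible peaks within 1 kb at 49.7% of 443 genes in WT (95% Wilson interval 45.03 to 54.3), 52.6% in R553H-MAFK (47.9 to 57.2), 45.1% in R553H-Sox2 (40.6 to 49.8) and 13.5% in R553H (10.7 to 17.0). R553H replicate 1 alone reached 56.7%, and replicate 2 alone 14.0%. Protein-coding genes at the same distance had 30.1%, 22.5%, 7.75% and 9.37% in that order, and 43.3% in R553H replicate 1 alone. Without chromosome 6, where many tRNA genes cluster, the tRNA shares were 44.8%, 49.7%, 33.0% and 17.7%. WT, R553H-MAFK and R553H-Sox2 had 137 tRNA genes in common, against 52.2 if they were independent, and 35 were in all 4 constructs. Small nuclear RNA genes had 22.7% in WT, 24.03% in R553H-MAFK, 19.5% in R553H-Sox2 and 11.7% in R553H, where replicate 1 alone had 22.1%. Neighbouring genes share peaks, and no test was run on these shares.

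Stronger regions of replicate 1 were shared more often in the comparisons given here, least clearly for WT in R553H. From the lowest to the highest of 5 groups by fold, the share of R553H replicate-1 regions found in WT was 65.8% and 95.2%, in R553H-MAFK 56.6% and 91.5%, and in R553H-Sox2 33.1% and 84.6%. For R553H-MAFK replicate 1 in WT it was 12.9% and 67.2%, and for R553H-Sox2 replicate 1 in WT 34.6% and 75.4%. WT replicate-1 regions were found in R553H-MAFK at 55.9% and 68.2%, and in R553H-Sox2 at 34.7% and 61.4%. WT replicate 1 in R553H had no such steady rise, with 45.7%, 39.0%, 40.0%, 44.9% and 52.3% over the 5 groups.

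The block inside FOXP2 appeared at high fold in replicate 2 of R553H, R553H-MAFK and R553H-Sox2. Its ends differed by at most 2 bp among these libraries. For comparison, the 100 strongest regions shared by each pair of these libraries were taken, 300 comparisons that can repeat a place. Their ends differed by at least 31 bp and by a median of 478.5 bp. A DNA fragment with fixed ends brought in with these samples is therefore a candidate explanation. The block was not called throughout batch 2: WT replicate 2 had only a region of 962 bp with other ends there, at a fold of 5.53. In batch 1 the highest fold percentile over the block was 71.4, below the rank set for binding of the R553H-based proteins there. The block was singled out for this contrast between batches, so the rank cannot decide against binding. Weaker regions were called there in R553H and R553H-MAFK replicate 1. Where such a fragment might come from was not tested.

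R553H replicate 2 held far fewer regions than replicate 1. Replicate-1 regions found again in replicate 2 had a median fold percentile of 79.4, against 43.6 for those not found, which is consistent with fewer sites passing the threshold. Whether these are sites of the same kind stays open, since those found were more often at gene ends (45.1% against 37.4% of those not found), although gene-end regions were the weaker ones. Replicate 2 as only the strongest part of replicate 1 is argued against, since as many strongest replicate-1 regions had a gene-end share of 24.9%, below the 44.1% (42.6 to 45.6) of replicate 2. Depth, enrichment and the amount of bound protein stay open, and no biological explanation was tested.

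Nearly all R553H peaks lay in WT regions when full lists were used, and 55.3% with lists of equal length. Chance overlap with the long WT list is argued against, since shuffled peaks reached at most 3.27% and locally shifted peaks 4.49%, against 96.9%. Of the 3522 peaks in WT, 2494 (70.8%) were also in both fusions, which is consistent with sites recovered in every EGFP ChIP whatever the construct. The remaining sites include 376 in neither fusion, of which 76.6% lay at gene ends. Binding by the R553H protein itself stays open as well, because the fusions also carry R553H, and the control ChIP that would separate these is not analysed here.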
